A study of Heliocidaris crassispina with 32 samples.

How the data were processed

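The data are single-cell RNA sequencing libraries of the sea urchin Heliocidaris crassispina, 32 samples in 4 groups of 8, grouped and numbered by their titles. The labels call the library source single cell, while the labels' protocol text describes a total RNA kit and an mRNA library kit of the bulk type, so the cell isolation and capture are not given in the sources used here. The deposited matrices hold whole-number UMI counts per gene and barcode, not normalised, with software version 10.0.0 per the file headers. The aligner, genome build and annotation are not given in the sources used here. Each deposited matrix held called cells, with barcodes of at least 330 UMIs in every library. The labelled libraries use 25525 gene identifiers, and the deposited pooled table of each stage uses 19491 identifiers of another series. In both, the name column repeats the identifier for every gene, so the files do not pair identifiers with names, and no reference table was used here. The gene lists and cell type markers fixed in advance could therefore not be matched, no gene list was tested and no cluster was named. The design kept all comparisons as successive stages: competent larva against eight-armed larva, new juvenile against competent larva, and competent juvenile against new juvenile.

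Libraries of a stage were compared by barcode and count. The noise measure was the variance of the difference between 2 libraries over its Poisson value, taken over entries with a summed count of at most 5, and over the total counts of cells. For entries, tested on simulated libraries of equal depth with 1000 cells and 25525 genes per stage, it gave 0.997 to 1.00 for independent molecules, between 0.543 and 0.547 when each library recovered the same molecules with a chance of 0.5, and between 0.234 and 0.236 with a chance of 0.8. All libraries of a stage shared cells, so the counts were summed per barcode into 1 library per stage, the file deposited under 2 numbers being counted once, which left 31. Barcodes with at least 200 detected genes were kept, 21699 of 21734. The edgeR quasi-likelihood test planned for the comparisons needs replicates, so with 1 independent library per stage no test was run and the planned fallback was used. Summed counts were 101124106 in the eight-armed larva, 23250094 in the competent larva, 22192348 in the new juvenile and 53721523 in the competent juvenile. The labels give the stages the same library numbers, but same-numbered libraries are runs of different cells and do not pair the stages.

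Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3, filterByExpr before the factors), which were 0.783, 1.23, 1.06 and 0.981 in stage order, and given as CPM, normalised counts scaled to a common library total. Differences are log2 of CPM with 1 CPM added, which understates the change of low genes. Genes were counted by a rule of size, at least 4-fold apart and at least 10 CPM in the higher library, which describes the libraries and is not a test. The named identifiers are the 2 furthest higher and the 2 furthest lower at that level; the rule fixed in advance asked for 10 of each with a gene name, and every identifier lacked one. Exact 95% Poisson intervals and exact conditional intervals of ratios were taken from the deepest library of each stage, and against a count of 0 the fold is a lower bound at 3 counts. Libraries were also simulated at the depth of the deepest ones, with 200 of 25525 genes changed 8-fold. The rule found 99.5% of them for competent larva against eight-armed larva and 100% for the other pairs, and 0 unchanged genes. The changed genes were drawn only from those well above 10 CPM and changed by more than 4-fold, so high recovery was built in. Recovery of genes near either limit was not measured. The simulation held Poisson noise only, without variation between cells or libraries, so the 0 says nothing on false passes from those sources.

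Cells were clustered with scanpy 1.11.5 after scaling to 10000 counts per cell and log transformation, on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden method at resolution 0.8. A cluster counted as mostly juvenile when juvenile cells made up over 50% of it after each stage was given equal weight, and as single-stage when 1 stage made up at least 90%. Scrublet called 4 doublets among 21699 cells, which were left out of the clustering and kept in the sums; so few calls were not relied on and doublets may remain, and leaving out the 5% of cells with the highest scores was added as an alternative. For genes per cell, 500 UMIs were drawn from each cell of the deepest library, leaving out 61, 87, 31 and 23 cells in stage order. The comparison with fixed cluster shares used the mean of the 2 libraries' shares over clusters with at least 20 cells in both. Intervals of shares are 95% Wilson intervals and cover counting error only. Figures were drawn with matplotlib 3.10.9.

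Alternatives planned before the data were examined were median-ratio factors, library totals, no filter on low counts, a fit of the 2 stages compared, at least 500 genes per barcode, thinning to 22192348 counts, labelled libraries as replicates with and without their number as a block, and resolutions of 0.4 and 1.2. Alternatives chosen after seeing the data were the deepest and the deep libraries alone, equal weight for every cell, leaving out the barcode with the most UMIs, leaving out each gene's highest barcode, 5 CPM as the added value, the pooled tables, thinned cells, clustering without the stage-differing or the 100 most abundant genes of each stage, leaving out high doublet scores, equal cluster weights, clusters from all genes, and every recount of genes by stage pattern. Equal weight for every cell averaged each gene's share over the cells and used no TMM factors, so it changed weighting and scaling together. A second copy of each pooled table was not used.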

Results

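Single cells of the sea urchin Heliocidaris crassispina were sequenced at 4 stages around metamorphosis, the change from a swimming larva to a bottom-living juvenile. The stages were the eight-armed larva, the competent larva, which is the larva that is able to metamorphose, the new juvenile and the competent juvenile. Each stage had 8 labelled libraries, 32 in all, and each library is a table of UMI counts, the number of distinct tagged RNA molecules per gene and cell barcode. Totals per library ran from 2240723 to 24209275 UMIs in the eight-armed larva and from 888355 to 4907413 in the competent larva. They ran from 897763 to 4703865 in the new juvenile and from 1274498 to 16110604 in the competent juvenile.

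**Figure D1:**
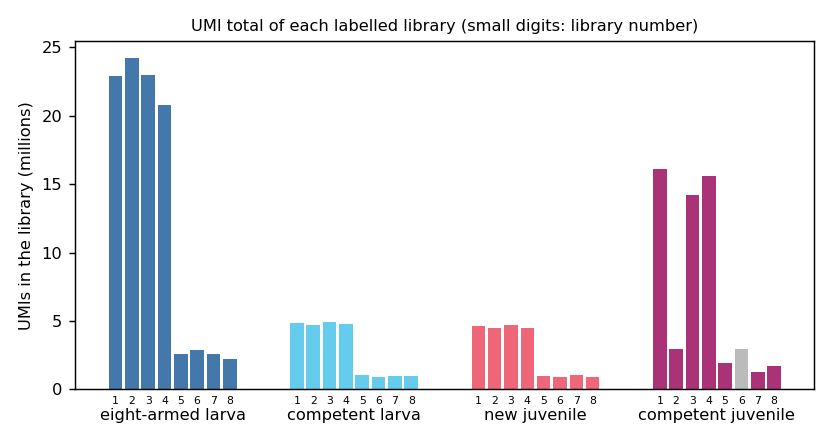
UMI total of each of the 32 labelled libraries, grouped by stage, with the library number under each bar; the grey bar is the competent juvenile library whose file is identical to that of library 2. Libraries 1 to 4 are the deep ones in 3 of the stages, up to 24209275 UMIs, and in the competent juvenile libraries 1, 3 and 4 are deep.

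The 8 libraries of a stage held the same cells. Any pair of libraries of the same stage shared between 96.3% and 100% of the barcodes of the smaller library, over 111 pairs, whereas libraries of different stages shared between 0% and 0.765%, over 384 pairs. Between libraries of like depth, the counts of a gene in a cell also differed by less than the sampling noise of independent molecules, with a variance of the difference between 0.147 and 0.896 of its Poisson value over 48 pairs. For the total count of a cell that ratio was between 0.114 and 0.877 in the same pairs, but between 1.25 and 6.54 in 63 pairs of a deep and a shallow library. For the counts of a gene in a cell it was between 0.549 and 0.842 in those 63 pairs, though the measure was not simulated at unequal depth. Libraries 2 and 6 of the competent juvenile were identical files. The labelled libraries were therefore summed into 1 library per stage and counted as 1 sample, so no stage had an independent replicate and no difference between stages was tested. The summed libraries held 8940 cells in the eight-armed larva, 3517 in the competent larva, 2341 in the new juvenile and 6901 in the competent juvenile. Because summing counts many molecules more than once, counting intervals were taken from the deepest library of each stage, with medians of 1641, 973, 1061 and 1448 UMIs per cell in the same order. These intervals cover counting error only, not the difference between animals or dissociations. Genes carry identifiers that the files do not pair with names, and 2 that were higher and 2 that were lower are given for each comparison.

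The first comparison asked which genes differed between the larva that had become competent and the eight-armed larva. In the competent larva 634 genes were at least 4-fold higher and 573 at least 4-fold lower, among 7717 genes that reached 10 CPM in the higher library. The identifier furthest above the eight-armed larva was HcCAS_21257, with 3720 UMIs (616 CPM, 95% Poisson interval 597 to 636) in the deepest competent larva library and 0 in the eight-armed larva. Set against a limit of 3 counts, that is at least 3893-fold higher. HcCAS_12275 had 3599 UMIs against 2, a ratio of 5650 (95% interval 1563 to 46670). In the new juvenile they were at 1148 and 461 CPM. Their counts came from very few cells: in the competent larva and again in the new juvenile, 2 barcodes held 90% of the UMIs of each. In the new juvenile 1 barcode held 58.5% of the UMIs of HcCAS_21257 and 76.0% of those of HcCAS_12275. With each gene's highest barcode left out, the log2 differences were 8.33 and 8.36, against 9.51 and 9.23 with all barcodes. With every cell weighted equally, here and below without TMM factors, they were 7.37 and 7.15.

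Among identifiers that were lower in the competent larva, HcCAS_03735 had 1464 UMIs in the deepest eight-armed larva library and 2 in the competent larva, a ratio of 233 (95% interval 64.4 to 1927), with 677 barcodes needed to reach 90% of its UMIs. It was back at 88.0 CPM in the new juvenile and stood at 54.5 CPM in the competent juvenile, so its low level was found in the competent larva alone. HcCAS_21514 had 1579 UMIs against 1, a ratio of 503 (95% interval 90.1 to 19877), and 46.9% of its UMIs in the eight-armed larva came from 1 barcode. Without that barcode its log2 difference was -5.32, against -6.06 with it. With at least 500 genes per barcode it was -5.08. With every cell weighted equally the log2 difference of HcCAS_03735 was -5.05, against -5.93.

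The split between higher and lower genes in this comparison followed the scaling. The 10 most abundant genes took 18.5% of the UMIs of eight-armed larva cells thinned to 500 UMIs and 8.80% in the competent larva. With library totals in place of TMM factors, 1300 genes were higher and 302 lower, and the median of all genes moved from -0.04 to 0.69 on the log2 scale. With every cell weighted equally the split was 983 to 323, at a median of 0.59. That setting also left out the TMM factors, so the weighting of cells cannot be told apart from the scaling. With factors from these 2 stages alone it was 552 to 635, at a median of -0.19.

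The second comparison spanned metamorphosis. In the new juvenile 557 genes were at least 4-fold higher and 731 at least 4-fold lower than in the competent larva, among 7653 at 10 CPM or more. HcCAS_21933 had 15127 UMIs (3041 CPM, 95% interval 2993 to 3090) in the deepest new juvenile library and 0 in the competent larva, at least 6118-fold higher. HcCAS_20660 had 22719 UMIs against 3, a ratio of 9189 (95% interval 3144 to 44559). Both remained high in the competent juvenile, at 2388 and 5840 CPM. In the new juvenile, 47 barcodes held 90% of the UMIs of HcCAS_21933 and 69 held 90% of those of HcCAS_20660. In the competent juvenile 14 barcodes held 90% of the UMIs of each. Their log2 differences across metamorphosis were 11.04 and 11.45 with each gene's highest barcode left out, against 11.62 and 11.58, and 10.70 and 10.34 with every cell weighted equally.

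Among the genes that were lower after metamorphosis, HcCAS_17336 had 6011 UMIs in the deepest competent larva library and 9 in the new juvenile, a ratio of 550 (95% interval 290 to 1204). In the competent larva 86.4% of its UMIs lay in 1 barcode, and its log2 difference was -5.97 without that barcode against -8.72 with it. In the eight-armed larva it stood at 2420 CPM, spread so that 22 barcodes held 90% of its UMIs. HcCAS_13630 had 8716 UMIs against 36, a ratio of 200 (95% interval 144 to 285). Its level was 1532 CPM in the eight-armed larva and 1444 in the competent larva, then 7.24 in the new juvenile and 18.6 in the competent juvenile. With every cell weighted equally the log2 difference of HcCAS_17336 was -6.43, and that of HcCAS_13630 was -6.89 against -7.78. With library totals in place of TMM factors, 495 genes were higher and 869 lower across metamorphosis, at a median of -0.25 over all genes.

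The third comparison followed the juvenile from the new to the competent stage, and fewer genes differed: 281 were at least 4-fold higher and 219 at least 4-fold lower, among 7510. HcCAS_10333 had 57300 UMIs (3630 CPM, 95% interval 3601 to 3660) in the deepest competent juvenile library and 5 in the new juvenile, a ratio of 3612 (95% interval 1548 to 11124). HcCAS_10329 had 103487 UMIs against 56, a ratio of 582 (95% interval 448 to 771). In the competent juvenile 14 barcodes held 90% of the UMIs of HcCAS_10333 and 22 held 90% of those of HcCAS_10329. Their log2 differences were 11.09 and 9.06, and with every cell weighted equally 8.68 and 7.16. HcCAS_08136 was at 119 CPM in the eight-armed larva, 3234 CPM in the competent larva and 96.3 CPM in the new juvenile. In the competent juvenile it had 1 UMI against 479, a ratio of 1520 (95% interval 271 to 60152), and its log2 difference was -6.41, or -7.07 with every cell weighted equally. HcCAS_22385 was high in the new juvenile alone, with 769 UMIs there, 17 in the competent juvenile, 0 in the competent larva and 3 in the eight-armed larva. Its ratio between the juvenile stages was 144 (95% interval 89.0 to 248). With library totals the split between the juvenile stages was 259 to 259, at a median of -0.15 over all genes, and with every cell weighted equally it was 290 to 321, also at -0.15.

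**Figure D2:**
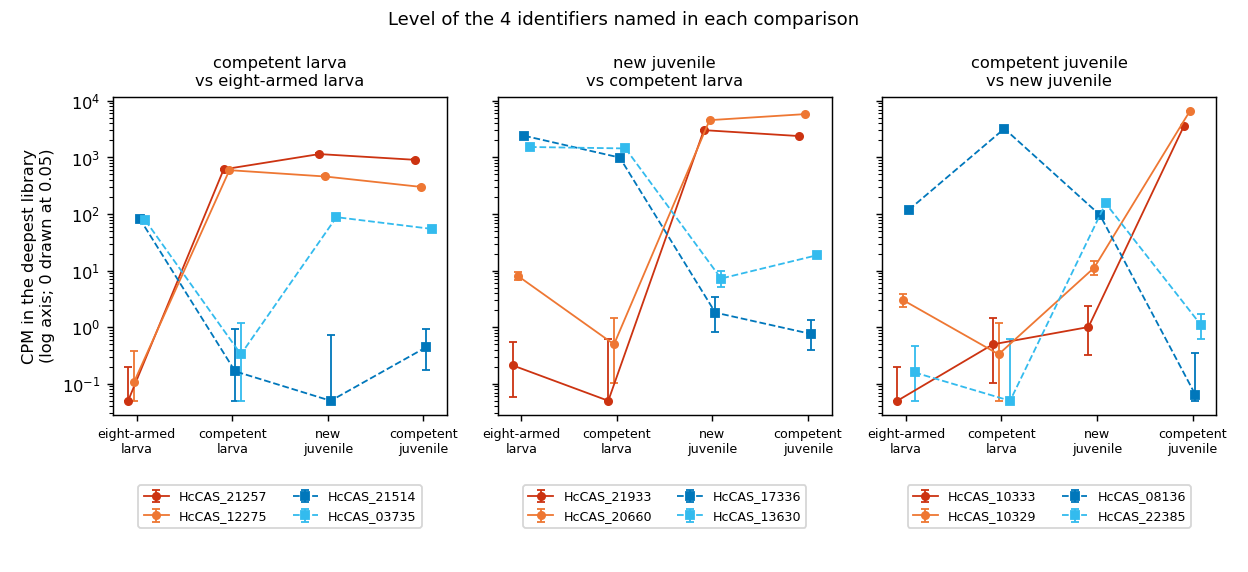
Level of each named identifier in the deepest library of the 4 stages, in CPM on a log axis, with 95% Poisson intervals for counting error; counts of 0 and interval ends below that point are drawn at 0.05. HcCAS_21257 is first high in the competent larva (616 CPM), HcCAS_21933 in the new juvenile (3041 CPM) and HcCAS_10333 in the competent juvenile (3630 CPM).

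Genes were also grouped by their profile over the 4 libraries, as those at least 4-fold higher in some stages than in every other stage, among 8742 genes at 10 CPM or more in any stage. In 101 genes both larval libraries were higher than both juvenile ones. These genes held 2.71% of the normalised counts of the eight-armed larva and 1.66% of the competent larva, against 0.0442% in the new juvenile and 0.0212% in the competent juvenile. In 174 genes both juvenile libraries were higher, and these held 3.75% and 7.21% of the counts in the new and competent juvenile against 0.0603% and 0.244% in the eight-armed and competent larva. A further 182 genes were higher in the competent larva and both juvenile libraries than in the eight-armed larva, with 0.0761% of its counts against 2.25%, 3.28% and 5.42% in the later stages. Genes higher in 1 stage alone numbered 191 in the eight-armed larva, 273 in the competent larva, 71 in the new juvenile and 139 in the competent juvenile. These counts moved with the scaling: in the same order they were 106, 459, 75 and 127 with library totals, and 113, 277, 125 and 122 with every cell weighted equally. The genes higher from the competent larva on then numbered 308 and 352. With 5 CPM added in place of 1, the larval genes numbered 47, the juvenile genes 92 and those from the competent larva on 60, and the genes of 1 stage alone 128, 166, 43 and 88.

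**Figure D3:**
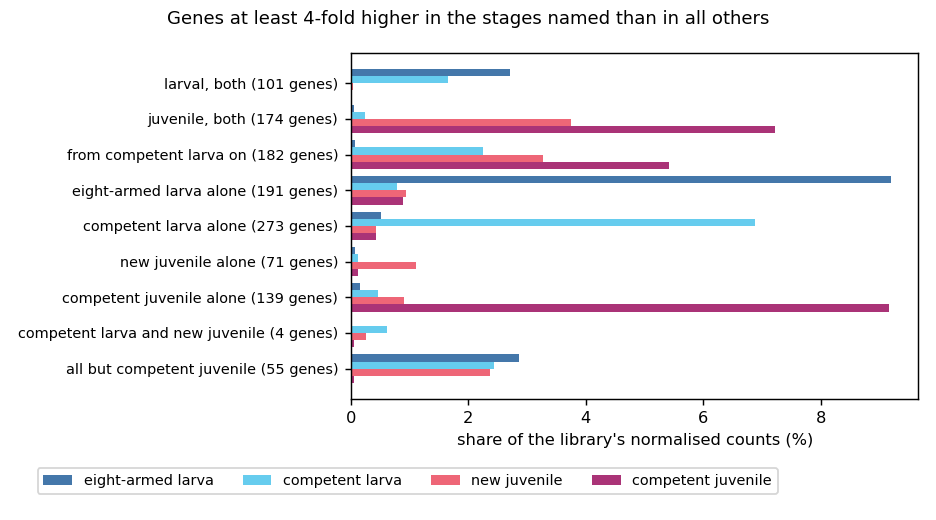
Share of each library's normalised counts, in percent, held by genes at least 4-fold higher in the named stages than in all others; bars are single summed libraries and have no replicate error. The larval genes hold 0.0442% and 0.0212% of the counts in the juvenile libraries, and the 139 competent juvenile genes hold 9.16% in that stage.

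Cells of the 4 libraries were clustered together to ask which cells were shared between stages. Genes that define clusters also differed between stages, so shares are given first from a clustering that left out 2530 genes. These genes were at least 4-fold apart between successive stages by library totals, not with TMM factors. Library totals passed 936 of the 1207 genes of the first comparison, so some genes that differed with TMM factors can have stayed in. Of the 16 clusters made without the 2530 genes, 9 held mostly juvenile cells after weighting the stages equally. These held 5.97% of eight-armed larva cells (95% Wilson interval 5.50 to 6.48), 23.0% of competent larva cells (21.6 to 24.4), 89.1% of new juvenile cells (87.7 to 90.3) and 93.5% of competent juvenile cells (92.9 to 94.1). With all genes, the same shares were 1.06%, 25.8%, 94.8% and 99.6% over 22 clusters. Shares rest on 1 library per stage, and dissociation and capture can set them.

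Cluster 4 held 36 eight-armed larva cells, a share of 0.403% (95% Wilson interval 0.291 to 0.557), and 308 competent larva cells, 8.76% (7.87 to 9.75). In the new juvenile it held 554 cells, 23.7%, and in the competent juvenile 1355 cells, 19.6% (18.7 to 20.6). In the competent juvenile this cluster held 99.1% of the UMIs of HcCAS_10333 and 98.3% of those of HcCAS_10329 after each gene's highest barcode was left out, though 14 and 22 barcodes carried 90% of all their UMIs. Cluster 8 held 0.0336% of eight-armed larva cells, 6.0% of competent larva cells, and 4.74% and 11.1% of the cells of the juvenile stages. Clusters 11, 12 and 14 stayed at or below 1.2% of the cells in both larval libraries. Cluster 11 held 12.6% of new juvenile and 7.91% of competent juvenile cells, whereas cluster 12 held 0.684% and 10.3%, and cluster 14 held 0.855% and 8.11%. In the other direction, clusters 1 and 2 held 39.6% and 26.9% of eight-armed larva cells and at most 5.46% and 2.09% in the later stages. Cluster 3 held 56.9% of competent larva cells and at most 3.38% elsewhere, so it may be that library and not a cell type. The clusters were left without cell type names, because no identifier could be matched to a marker gene.

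**Figure D4:**
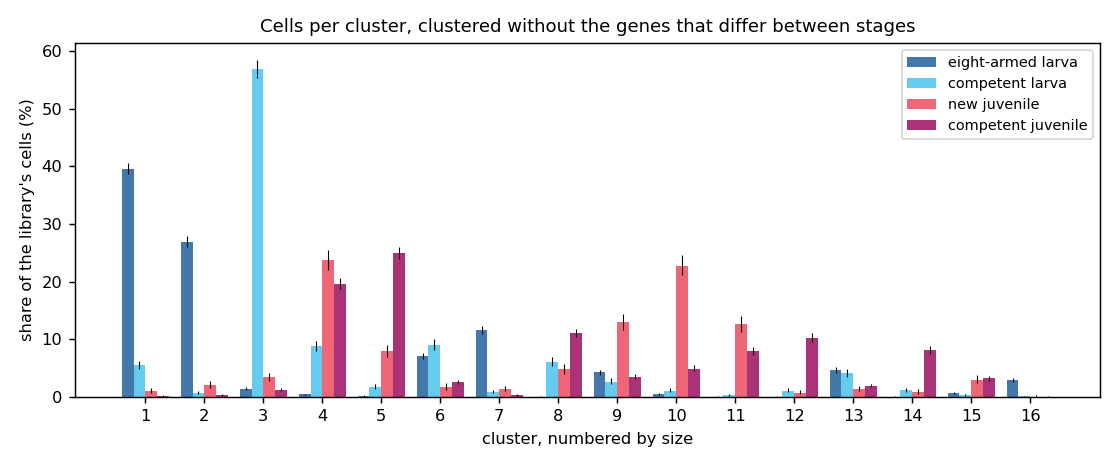
Share of each library's cells in the 16 clusters, in percent, clustered without the 2530 genes at least 4-fold apart between successive stages by library totals. Bars are single libraries and lines are 95% Wilson intervals for counting error. Clusters 1 and 2 are mostly eight-armed larva cells, cluster 3 is mostly competent larva cells, and cluster 4 holds 0.403% and 8.76% of the larval libraries.

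To see how far the gene differences followed the shares of clusters, levels were compared again with the cluster shares held fixed over clusters with at least 20 cells in both libraries. Of the 1207 genes that differed at least 4-fold between the competent and eight-armed larva, 700 were still at least 4-fold apart in the same direction over 9 shared clusters, and 1097 were at least 2-fold apart, while 12 changed direction. Across metamorphosis 567 of 1288 remained at least 4-fold and 1129 at least 2-fold apart over 12 shared clusters, and 5 changed direction, or 23 with every cluster weighted equally. Between the juvenile stages 280 of 500 remained at least 4-fold and 466 at least 2-fold apart over 13, and 1 changed direction. The clusters shared by a pair of libraries held between 83.8% and 98.3% of their cells. These clusters were made without the 2530 stage-differing genes, so they can hold together cells that differ in those genes. Differences kept within them can therefore still come from a mix of cells. With clusters made from all genes, 424 genes of the first comparison remained at least 4-fold apart and 297 (24.6%) changed direction, over 2 shared clusters that held 1.71% of competent larva and 14.6% of eight-armed larva cells. In the second, 347 remained and 14.4% of the 1288 changed direction, over 7 shared clusters. These held 47.0% of new juvenile and 81.2% of competent larva cells. In the third, 273 of 500 remained and 1 (0.2%) changed direction, over 9 shared clusters. These held 99.4% of competent juvenile and 77.5% of new juvenile cells.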

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

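The check of each library against the others of its stage was fixed in advance, and the look at the pooled table was chosen after it was seen. For barcodes, UMI total, UMIs per barcode and genes per barcode, 0 of 32 checks of the highest and lowest library of a stage passed the 95% limit. The split into deep and shallow libraries sets the range against which each gap was measured, so these checks say nothing on whether a library stands apart.

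A signal lies in data that the comparisons did not use. The pooled table of the competent juvenile holds sub-library 2 with 7279 barcodes, 17840415 UMIs and a median of 1477 UMIs per barcode, the largest of its 4 sub-libraries. The labelled competent juvenile library 2 holds 2342 barcodes and 2928701 UMIs and is the same file as library 6. The deep library of that number was thus not used in the competent juvenile values above, and the pooled table was used as an alternative only.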

How the results depend on the processing

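Chosen after seeing the data were the added value of 5 CPM, clusters from all genes, thinned cells, the clusterings without stage-differing or abundant genes, the deepest libraries alone, the pooled tables and the other additions named with the processing. Across the planned and added alternatives run, 42 recounts of genes at least 4-fold apart stayed within 1.5 times the reported count and 3 did not. That tally compares totals, not directions or which genes passed. It also holds the settings with labelled libraries as replicates, with and without the library number as a block. Those settings only filtered the reported genes, so their counts could not exceed the reported ones and cannot show genes gained. With library totals, 936 of the 1207 genes of the first comparison were among the 1602 found. With every cell weighted equally, 375 of the 500 between the juvenile stages were among the 611 found. Of the 144 recomputed log2 differences of named identifiers, 36 moved outside the counting interval and 0 changed direction, the smallest being 3.96 in size. The identifiers were picked as the furthest apart, so a change of direction was hardly possible. With 5 CPM added in place of 1, the counts were 713 for competent larva against eight-armed larva, 824 across metamorphosis and 263 between the juvenile stages, since a larger added value lowers every fold. Of the recounts of genes by stage pattern, all added after seeing the data, 92 stayed within 1.5 times the reported count and 16 did not. With clusters made from all genes, the counts at fixed cluster shares were 424 for the first comparison, 347 for the second and 273 for the third. In the same order, 24.6%, 14.4% and 0.2% of the genes changed direction, and only 2, 7 and 9 clusters were shared by both libraries.

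Taking the labelled libraries as replicates, with and without the library number as a block, describes repeat runs of the same cells and not the stages. With the block, 1207, 1287 and 497 of the genes past the size rule also had an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg) in comparison order, and without the block the counts were the same. The test without the block called 84.9%, 75.8% and 79.3% of 11712 genes, and with the block 86.3%, 78.0% and 81.0%.

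The share of cells in mostly juvenile clusters moved outside the counting interval of the all-gene clustering (1.06%, 25.8%, 94.8% and 99.6%) as follows, with stages in the order eight-armed larva, competent larva, new juvenile and competent juvenile. Without stage-differing genes it was 5.97%, 23.0%, 89.1% and 93.5%, and without the 100 most abundant genes of each stage 3.31%, 23.0%, 92.0% and 96.8%. With cells thinned to 500 UMIs it was 8.23% in the eight-armed larva, 34.4% in the competent larva and 99.1% in the competent juvenile. At resolution 0.4 it was 34.4% in the competent larva and 99.8% in the competent juvenile. With at least 500 genes per barcode it was 96.8% in the new juvenile and 99.8% in the competent juvenile, in the deepest libraries alone 95.8% in the new juvenile, and in the pooled set 98.8% in the competent juvenile. In each of these settings the order of the stages was the same; the cause of the moves was not tested. DESeq2, leaving out a library, and merged library numbers as a block gave no value, since each stage has 1 independent library, and no list test was run because no identifier has a name. Depth limits the ratios of identifiers with 0 to 3 UMIs in their lower library, which have wide intervals or a bound only.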

Other observations

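Chosen after the result was seen were the tests of restriction to clusters, of thinned cells, of library preparation and of barcodes shared with juvenile libraries, the bootstrap interval and noise removal of the per-cell correlation, and the limit of 80% for clusters of 1 stage. Genes that marked stages were also restricted to few clusters. An index of restriction, 0 for equal levels in every cluster and 1 for a single cluster, was computed without each gene's highest barcode. Its median was 0.943 in the competent juvenile for genes high in both juvenile stages, against 0.720 for random lists matched on level (95% of 10000 lists between 0.675 and 0.760). For genes high from the competent larva on it was 0.931 in the competent larva, against 0.715 (0.685 to 0.742). It was 0.909 in the eight-armed larva for genes high in both larval stages, against 0.685 (0.638 to 0.732), and 0.806 for genes of the competent larva alone, against 0.683 (0.659 to 0.708). Each of these medians lay above all 10000 random lists. Of the 182 genes high from the competent larva on, 150 reached 10 CPM in the competent larva, where 70 were highest in cluster 4. In the new juvenile 172 reached 10 CPM, and 100 were highest in cluster 4. That cluster held 0.403% of eight-armed larva cells and 8.76% of competent larva cells, so its genes can enter this pattern through cell shares alone. How many of all genes were highest in cluster 4 was not counted.

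Cells thinned to 500 UMIs had a median of 257 genes in the eight-armed larva, 329 in the competent larva, 312 in the new juvenile and 281 in the competent juvenile. Unthinned, the order was different, with 604, 513, 527 and 576 genes. In the new juvenile, 1 barcode held 1743959 summed UMIs, 7.86% of its library and 433 times the median, with 10081 genes detected; the next barcode held 347828. Of the 1288 genes past the size rule across metamorphosis, 38 had over 50% of the higher library's UMIs in 1 barcode. Counts of the same cells in the pooled tables paired 7879 of 13440 identifiers with 1 of the other series at a correlation of at least 0.8.

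Genes whose identifiers have consecutive numbers tended to differ between stages together: across metamorphosis 101 consecutive pairs passed the size rule in the same direction, against a median of 47 and a highest count of 73 in 10000 shufflings of the calls. The pairs numbered 99 against a highest of 66 for the competent against the eight-armed larva, and 31 against 18 between the juvenile stages, so a chance order can be excluded as the whole cause. Single genes split into pieces were predicted to give over 50% of pairs a shared partner in the other identifier series, but 3.39% of 118 pairs did. In those pairs this argues against pieces of 1 gene that the other series holds whole. Only 118 of 193 pairs had a partner for both members at a correlation of at least 0.8. A piece with few counts can miss that limit, and the other series can hold the same pieces, so split genes are not excluded. Reads shared between near-identical copies cannot be told apart from joint regulation: the median per-cell correlation of a pair, 0.233, was under the limit of 0.3 set beforehand to exclude them, but its 95% bootstrap interval of 0.175 to 0.333 spans that limit, and it was 0.462 with counting noise removed. A candidate explanation is that neighbouring genes of a family are used at the same stage, but whether consecutive numbers are neighbours in the genome was not tested.

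Larval cells clustered apart by stage, with 89.5% of eight-armed larva cells and 73.2% of competent larva cells in clusters where 1 stage made up at least 90%. For the eight-armed larva the tables argue against a difference in UMIs per cell, since its share was 91.8% with every cell thinned to 500 UMIs. Whether a few abundant genes set its separation stays open, because the answer turns on the limit: without the 100 most abundant genes of each stage the share was 23.0% (27.8% in the competent larva), yet 63.9% of eight-armed larva cells still lay in clusters at least 80% of their own stage. Without the 2530 stage-differing genes the share was 4.32% (56.9% in the competent larva). Of the eight-armed larva cells, 2.89% then lay in clusters at least 90% of their own stage and 80.9% in clusters at least 80%. At the limit of 80% most of these cells thus still clustered apart. The 2530 genes were left out only after each cell was scaled, so they still set the scaling. Whether the separation lies in the genes that were kept was not tested. A difference between library preparations cannot be told apart from the stage, because each stage has 1 library, and the stage itself stays open and untested.

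Of the competent larva cells, 25.8% fell in clusters made mostly of juvenile cells, against 1.06% of eight-armed larva cells. Barcodes carried over from the juvenile libraries are excluded, since 0% of these 906 barcodes were found in a juvenile library, which allows up to 0.331%. A difference in UMIs per cell was predicted to lower the share on thinning to 500 UMIs, but it was 34.4%. The eight-armed larva share also rose, to 8.23%, so thinning itself moved cells into these clusters. The test therefore cannot exclude a difference in UMIs per cell. Metamorphosed juveniles as the source of the whole share would bring all their abundant transcripts in proportion. Yet of 95 genes at least 16-fold higher in both juvenile libraries than in the eight-armed larva, 36.8% lay under 0.1 of the level needed. Another 26 lay at or above it, and the median was 8.90% of the lower juvenile level. A smaller admixture was not tested and stays open. Such genes can sit in very few cells: 14 barcodes held 90% of the UMIs of HcCAS_21933 in the competent juvenile. Low levels can thus also come from which cells were captured, so mixing is not excluded. The hypothesis that competent larvae hold cells on the way to juvenile types, such as those of the juvenile rudiment, remains open; no marker could be named to test it.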
